A study of Caenorhabditis elegans with 4 samples.

How the data were processed

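ChIP-seq of a GFP-tagged LIN-39 protein was done in fed L1 hermaphrodites of 1 transgenic strain. Per the labels' protocols, worms were grown at 20 degrees C, fixed in formaldehyde at 2%, treated with Tris at 100 mM and sonicated, and chromatin was collected with an antibody against GFP, with part of the same extract kept as input. Samples were grouped by their titles into 2 ChIP libraries and 2 input libraries, each numbered 1 and 2. Interval lists were used for both ChIP libraries and for the whole series. Values of the input libraries were not used here, and whether the deposited intervals were called against them is not given in the sources used here.

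The intervals came from PeakSeq with coordinates on WormBase WS220, per the file headers and the source column of the files. Each interval carries 1 significance value that the authors deposited, a p-value or q-value with no statement of which. All values are between 0 and 9.997e-04, so no list held an interval with a larger value. The value was used only to rank intervals within a list and to relate shared intervals. The PeakSeq version, its thresholds, the aligner and whether the reads of the replicates were pooled for the combined list are not given in the sources used here. Neighbouring intervals in a list were at least 202, 224 and 201 bp apart in replicate 1, replicate 2 and the combined list, so closer regions would appear as 1 interval. A library with more reads usually gives more and weaker intervals, and since no read numbers were used here, a difference in the number of intervals between lists cannot be separated from depth.

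Intervals were called shared when they overlapped by at least 1 bp. Chance overlap was estimated from 10000 circular shifts of 1 list along each chromosome, which keep the spacing of the intervals, with a one-sided p. Values of intervals that overlapped one to one were related by Spearman's rho and by Pearson's r of −log10 values, with 100000 permutations each, two-sided. The plan named Pearson's r on ranks, which equals Spearman's rho, so −log10 values were used instead. Shares have exact Clopper-Pearson 95% intervals. Chromosomes were compared with their lengths, and the middle 33.3% with the rest, by two-sided exact binomial tests with Benjamini-Hochberg adjustment over chromosomes. The files gave no chromosome lengths, and the plan was to skip these tests in that case. They were run with the largest interval end on each chromosome in any list as its extent. The X share of the strongest intervals was tested by rotating strengths along the genome order over every possible rotation, one-sided, and by Fisher's exact test. X is 1 block in that order, so small rotations keep strong X intervals on X and set a floor under the rotation p. All of these p-values and intervals cover counting error only, and the replicates may differ for technical reasons.

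The rule for names was fixed before the data were examined. It took lin-39, the other Hox genes and their cofactors, unc-119, members of gene lists, and the genes assigned to the 15 strongest combined intervals, with intervals named by position where no gene was assigned. The chromosome IV run and the single intervals and spans of the closing section fall outside this rule and were chosen after their values were seen. No genome or annotation of WS220 was used here, and positions were not converted between builds. Gene assignment, genomic features, gene lists, Hox and cofactor loci and the Hox motif were therefore not analysed here, and the 15 intervals are named by position. The gene table of assembly WBcel235 was used only for the chromosome of lin-39 and unc-119. Alternatives were another overlap rule, the stronger 50% of each list, uniform placement, each replicate list alone, intervals overlapping both replicate lists, covered bases and 10 kb windows. Further ones left out the windows of the densest and the widest intervals, or took other numbers of strongest intervals for the X share.

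Scripts used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, with random seed 39. The overlap test was tested on simulated data with lists of 3541 and 1739 intervals, where 296 of 300 planted shared intervals were recovered beyond chance. Of 20 pairs of unrelated lists, 1 had a p under 0.05. The planted intervals were copies moved by 1 bp, so their overlap was fixed and their recovery checks the counting only. The simulated lists were placed at random without clustering and used fewer shifts than the data, so clustered lists were not simulated.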

Results

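Binding of LIN-39, a Hox protein that patterns the mid-body of Caenorhabditis elegans, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in fed L1 larvae, the first larval stage. The strain carried a lin-39 transgene tagged with GFP together with a functional unc-119 gene, in an unc-119 mutant background, and the chromatin was collected with an antibody against GFP. The series held 4 libraries from this strain, 2 ChIP libraries and 2 input libraries of total chromatin DNA. Values of the input libraries were not used here. The data were 3 lists of enriched intervals, 1 for each ChIP replicate and 1 for the whole series, called the combined list below. The lists carried no read numbers, so the depth of each library is unknown, and each list is a single call without an error of its own. The labels did not say whether the replicates came from separate worm cultures, so differences between them may be technical. All positions are 1-based on WormBase WS220, and no gene annotation of that build was used here, so intervals are named by position.

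Enriched intervals were found on all 6 chromosomes in each list. The list of replicate 1 held 3541 intervals, 2.03 times the 1743 of replicate 2, and the combined list held 8006. Replicate 1 intervals covered 1515436 bp with a median width of 372 bp, and replicate 2 intervals covered 883002 bp with a median width of 430 bp. The combined intervals covered 2939357 bp, or 2.93% of the summed chromosome extents, with a median width of 287 bp. Very short intervals were part of the combined list, with 830 (10.4%) under 50 bp, against 156 in replicate 1 and 3 in replicate 2. At the other end, 44 combined intervals were at least 2000 bp wide. No test of these numbers was possible with 1 list per library.

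The first comparison asked whether the replicates found the same regions. Of the 1743 intervals of replicate 2, 1286 (73.8%, exact 95% interval 71.6 to 75.8%) overlapped an interval of replicate 1 by at least 1 bp. In the other direction, 1281 of the 3541 replicate 1 intervals (36.2%, 34.6 to 37.8%) overlapped replicate 2. When the intervals of 1 list were shifted together along the chromosomes, 57.6 of the replicate 2 intervals overlapped on average and at most 245 did. The observed number was 22.3 times the mean. Very small shifts of a chromosome were allowed and leave true overlaps in place, so the highest number may lie above the chance level. The one-sided permutation p was 1.000e-04, the smallest that 10000 shifts can give. The intervals around these shares cover counting error only, because neighbouring intervals are not independent.

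Regions with the strongest values were shared far more often than weak regions. Each list was divided into 5 equal groups by the authors' significance value. In replicate 1, 91.7% of the strongest group (89.4 to 93.6%, n = 709) overlapped replicate 2, followed by 50.3%, 22.3%, 10.2% and 6.36% in the weaker groups. In replicate 2, 99.4% of the strongest group (97.95 to 99.93%, n = 349) overlapped replicate 1, followed by 93.7%, 80.7%, 54.7% and 40.2%. Among the 100 strongest intervals, 100 of replicate 1 and 99 of replicate 2 were shared. The exception was the strongest interval of replicate 2, which overlapped no interval of replicate 1 or of the combined list. Widths fell with the same order, from a median of 579 to 192.5 bp in replicate 1 and from 605 to 312 bp in replicate 2, so a wide interval also had more room to overlap.

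**Figure D1:**
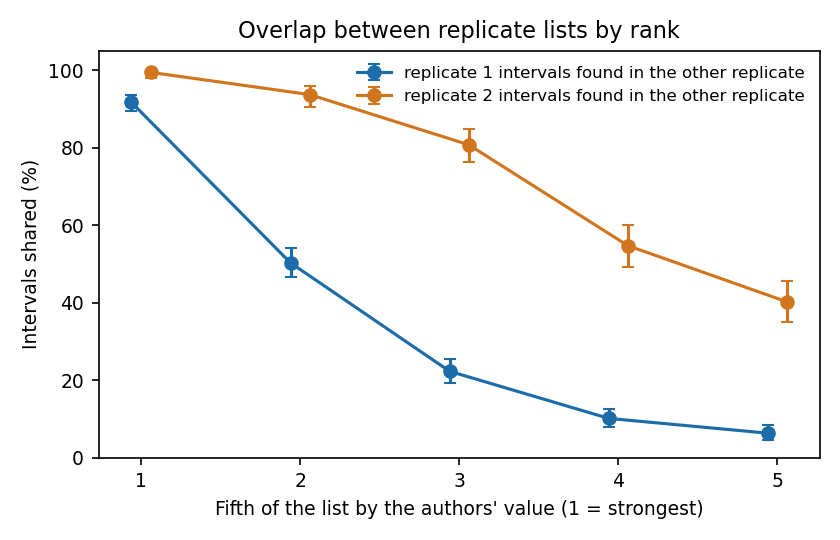
Share of the intervals of each replicate list (vertical axis, %) that overlap the other list by at least 1 bp, for 5 equal groups by the authors' value (horizontal axis, 1 is the strongest), with exact 95% intervals as bars. The share falls from 91.7% to 6.36% in replicate 1 and from 99.4% to 40.2% in replicate 2.

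Across the regions shared one to one, the strength order was similar in the replicates. For 1241 pairs of intervals, Spearman's rho between the values was 0.686 and Pearson's r between their −log10 values was 0.905. Each had a two-sided permutation p of 1.000e-05 (adjusted p = 1.000e-05 over both coefficients), the smallest that 100000 resamples can give. This relation is across intervals, which are not independent replicates, and it covers only intervals called in both lists.

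The combined list was compared with the replicate lists to see which regions it held. It contained 3213 of the 3541 replicate 1 intervals (90.7%, 89.7 to 91.7%) and 1665 of the 1743 replicate 2 intervals (95.5%, 94.4 to 96.4%). Of its own 8006 intervals, 1260 (15.7%, 14.9 to 16.6%) overlapped both replicate lists, 1934 (24.2%) overlapped replicate 1 alone and 378 (4.72%) replicate 2 alone. The remaining 4434 (55.4%, 54.3 to 56.5%) overlapped neither list. The combined list was therefore neither the union nor the intersection of the replicate lists. With 3541 and 1743 intervals, the replicate lists were much shorter than the combined list, which limits how much of it they could overlap. Support by both replicates was concentrated among strong regions, at 73.3% of the strongest of 5 equal groups, 4.68% of the next and 0.437%, 0.187% and 0% of the others. The 0 of 1601 intervals in the weakest group allowed a share of up to 0.230% (exact 95% upper bound). All 100 of the strongest combined intervals overlapped both lists, while 710 of the 830 intervals under 50 bp overlapped neither. The median width was 587 bp for combined intervals that overlapped both lists and 190 bp for those that overlapped neither. Wide intervals had more room to overlap here too, and support was not separated from width.

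**Figure D2:**
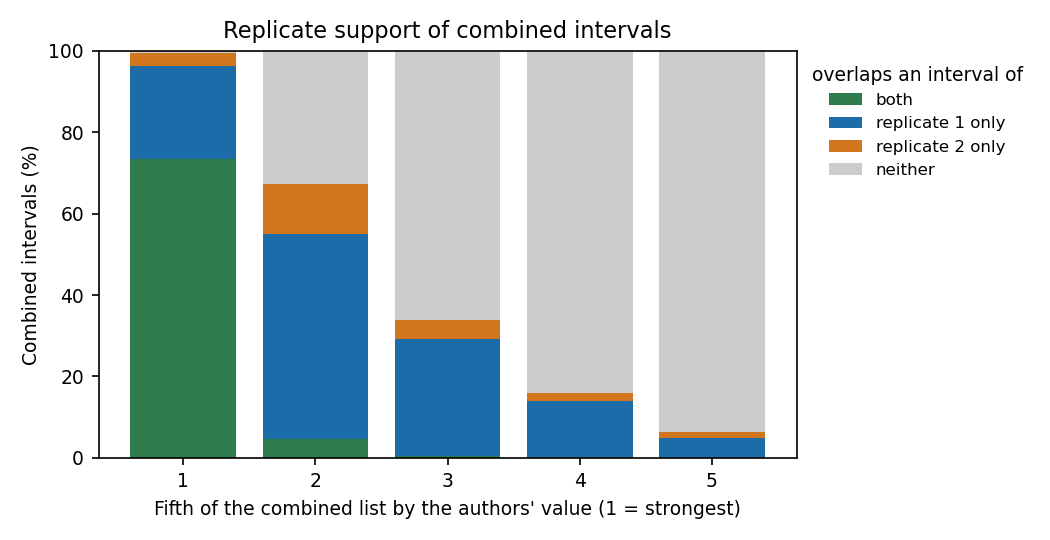
Share of combined intervals (vertical axis, %) that overlap both, 1 or neither of the replicate lists, as stacked bars for 5 equal groups by the authors' value (horizontal axis, 1 is the strongest). Support by both replicates falls from 73.3% in the strongest group to 0% in the weakest.

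The 15 strongest combined intervals, all of which overlapped both replicate lists, were spread over 5 chromosomes. The first was a 28411 bp interval on chromosome III at 7521404 to 7549814, the chromosome that carries lin-39 and unc-119 in the gene table of assembly WBcel235, with a value of 6.96e-140. Replicate 1 covered this region with intervals of 17755 and 8227 bp and replicate 2 with intervals of 16242 and 1577 bp, and the next widest combined interval was 5230 bp. Chromosome X held 9 of the 15. In rank order these X intervals were at 14525315 to 14526322 (value 3.84e-139), 11093557 to 11094419 (2.32e-121), 2996256 to 2997773, 13700137 to 13701263, 6740510 to 6744740, 12362713 to 12363461, 11605262 to 11607559, 8035704 to 8036984 and 9465366 to 9466180. Chromosome IV held the third interval, at 13695557 to 13697330 (value 4.67e-123), and another at 14032581 to 14034654. Chromosome II held intervals at 5543129 to 5544512 and 5844498 to 5845214, and chromosome V held 1 at 4507511 to 4508765. Apart from the chromosome III interval, widths ran from 717 to 4231 bp. Each of the 15 overlapped at least 1 replicate 1 interval ranked 55 or better in its list and at least 1 replicate 2 interval ranked 30 or better. At the chromosome III region, first in the combined list, the wider intervals ranked 12 in replicate 1 and 13 in replicate 2. The narrower intervals there ranked 150 in replicate 1 and 1095 in replicate 2.

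**Figure D3:**
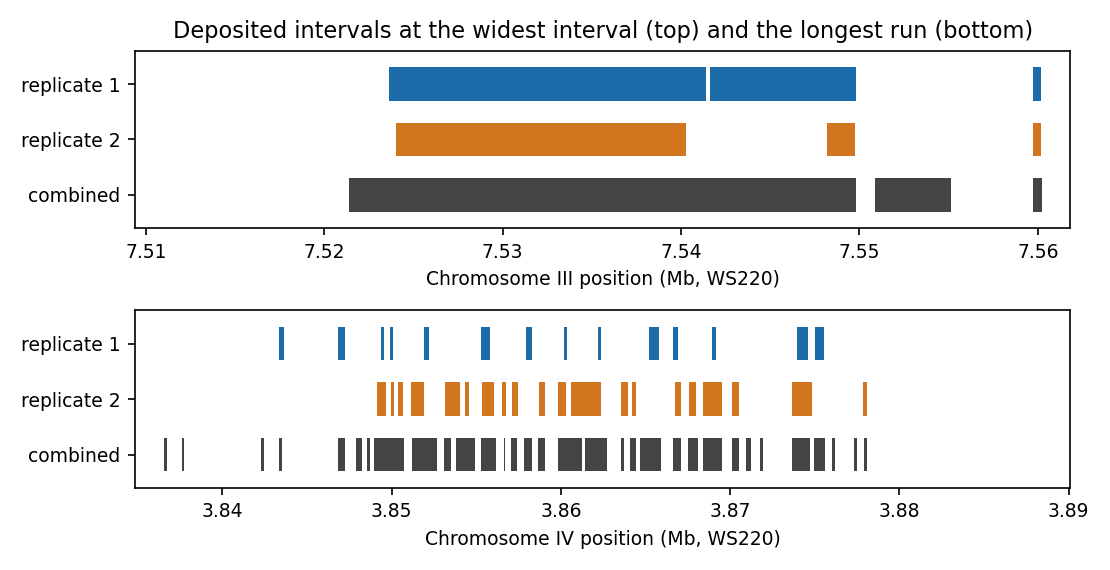
Intervals of the 3 lists (rows of bars) by position in Mb on WS220, at the 28411 bp interval of chromosome III (top) and at a run of 29 combined intervals on chromosome IV (bottom). Both replicates hold wide intervals inside the chromosome III interval, and replicates 1 and 2 hold 14 and 20 intervals in the chromosome IV run.

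The share of strong regions on X was examined after these intervals had been seen. X held 60% of the 15 strongest combined intervals (9 of 15, exact 95% interval 32.3 to 83.7%) and 14.4% of all combined intervals. With the strengths rotated along the genome, which keeps neighbouring strengths together, the one-sided permutation p was 0.0506 (adjusted p = 0.0716) and the difference did not pass 0.05. X is 1 block in this order, so small rotations leave the same strong intervals on X and set a floor under the p. The 10 and the 15 strongest combined intervals share their outermost X intervals and had the same permutation p of 0.0506. For these 15 the rotation test therefore could not decide. Fisher's exact test, which treats intervals as independent, gave a two-sided p of 5.820e-05 (adjusted p = 2.077e-04). The share was 60% in replicate 1 (9 of 15, permutation p = 0.0554, adjusted p = 0.0716) and 53.3% in replicate 2 (8 of 15, permutation p = 0.0889, adjusted p = 0.10). The adjusted values cover 18 comparisons, made with 6 numbers of strongest intervals in each of 3 lists. In the combined list the share was 40% of the 50 strongest (permutation p = 0.0139, adjusted p = 0.0491), 24% of the 100 strongest (permutation p = 0.0212, adjusted p = 0.0491) and 18% of the 200 strongest (permutation p = 0.168, adjusted p = 0.178), so the call depended on the number taken. Because of the floor, it also depended on how near the outermost strong X intervals lay to the ends of X. Passing or not therefore does not measure how large the X share is. Among the 25, 50 and 100 strongest, X held 60%, 34% and 25% in replicate 1 and 52%, 36% and 26% in replicate 2 (permutation test, adjusted p = 0.0491 for each of the 6). The 25 strongest combined intervals, with 56% on X, did not pass after adjustment (permutation p = 0.0307, adjusted p = 0.0615). Among the 200 strongest, the shares were 19.5% in replicate 1 and 18.5% in replicate 2 and did not pass (permutation test, adjusted p = 0.0834 and 0.213).

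Taking all intervals, chromosome IV held more and chromosome X fewer than their lengths predicted. In the combined list, IV held 1788 intervals, 1.28 times the number predicted (two-sided exact binomial test, adjusted p = 4.154e-28 over 6 chromosomes), and X held 1156, 0.818 times the number predicted (adjusted p = 3.586e-14). The ratios were 1.33 and 1.30 for IV and 0.838 and 0.871 for X in replicates 1 and 2, each past the test. Chromosome III held 0.903 times the predicted number (exact binomial adjusted p = 9.668e-04), but the ratio was 0.918 (adjusted p = 0.223) in replicate 2 and 1.01 (adjusted p = 0.870) for combined intervals that overlapped both replicate lists. Chromosomes I, II and V, at ratios of 0.956, 1.03 and 0.992, did not pass the exact binomial test (adjusted p = 0.146, 0.277 and 0.731). Chromosome I was nevertheless below 1 and past the exact binomial test in both replicate lists, at 0.888 (adjusted p = 0.00717) in replicate 1 and 0.717 (adjusted p = 8.363e-07) in replicate 2, and chromosome II was at 1.19 (adjusted p = 0.00216) in replicate 2. Chromosome lengths were replaced by the largest interval end in any list, a choice made after the data were seen, and p-values cover counting error only.

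**Figure D4:**
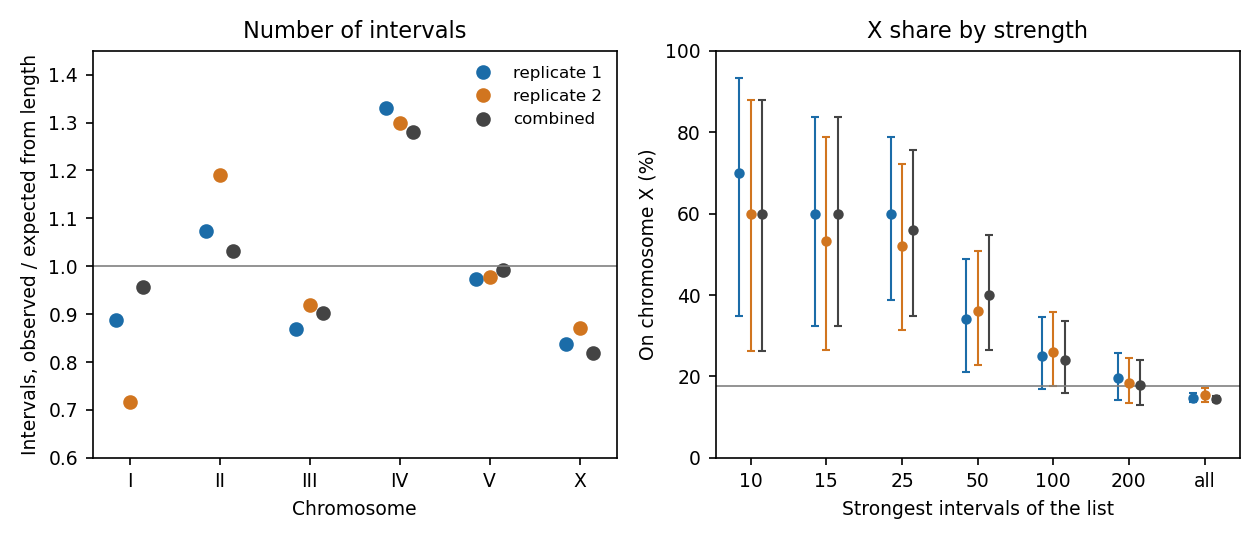
Left, number of intervals per chromosome divided by the number predicted from chromosome extent, for each list. Right, share of intervals on X (%) among the strongest 10 to 200 and all intervals of each list, with exact 95% intervals as bars and the X share of the summed extents as a line. IV lies at 1.28 to 1.33 and X at 0.818 to 0.871 in the left panel.

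Along the chromosomes, the middle 33.3% of each held 2411 of the 8006 combined intervals (30.1%, 29.1 to 31.1%), fewer than an even spread gives (two-sided exact binomial p = 7.526e-10). Replicate 1 was at 30.2% (exact binomial p = 8.772e-05) and replicate 2 at 35.1% (p = 0.127), on the other side of the even share. Combined intervals that overlapped both replicate lists were at 36.4% (33.8 to 39.2%, exact binomial p = 0.0214, adjusted p = 0.0285 over 4 groups by overlap with the replicates), above the even share. Those that overlapped neither were at 29.3% (27.98 to 30.68%, exact binomial adjusted p = 4.216e-08), and the difference of 7.11 percentage points between these groups had a two-sided p of 1.834e-06 by Fisher's exact test. Combined intervals that overlapped replicate 1 alone were at 27.97% (exact binomial adjusted p = 8.995e-07), and those that overlapped replicate 2 alone were at 29.4% and did not pass (adjusted p = 0.113). The direction for the whole genome thus depended on which intervals were counted. Each chromosome was also set against the even share, and differences between chromosomes were not tested. In the combined list, I, II, III, IV and X were below the even share, at 28.9% to 30.5%, and past the exact binomial test (adjusted p from 3.188e-04 to 0.0405), while V was at 33.3% (p = 1). In replicate 1, I, IV and X were below it and past the exact binomial test, at 28.3%, 27.3% and 28.05% (adjusted p = 0.0436, 0.00110 and 0.0322), and the others did not pass. In replicate 2, V was above it at 42.98% (exact binomial adjusted p = 9.501e-04), X was below it at 26.1% (adjusted p = 0.0345) and the others did not pass. The split by overlap with the replicates was chosen after the data were seen.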

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

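Tests of chromosomes, the middle 33.3% and the X share, along with 10 kb windows and other overlap rules for rank groups and for the value relation, were chosen after the data were seen. So was the replicate overlap without the windows of the densest and the widest intervals. Of 63 alternatives, 33 kept direction and side of the threshold or stayed within the error. The cause of the other changes was not tested. Replicate overlap stayed past the test throughout, at 63.2% to 88.98%. The median combined width was 441 bp in the stronger 50%. Support by both replicates was 13.1% with reciprocal overlap of 50% and 31.3% in the stronger 50%. With reciprocal overlap of 50% or midpoints within 200 bp, the strongest rank group was shared at 81.4% and 81.1% in replicate 1 and at 89.4% and 86.2% in replicate 2.

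In the stronger 50% of combined intervals, the chromosome ratio was 1.04 for I (turned in direction), 0.958 for III (no longer past the test), and 1.08 for II and 0.912 for V (now past it). With each replicate list alone, ratios were 0.717 to 0.888 for I, 1.07 to 1.19 for II and 0.869 to 0.918 for III, and the share in the middle 33.3% was 30.2 to 35.1%. For intervals overlapping both replicate lists, ratios were 0.813 for I and 1.20 for II, both now past the test, and 1.01 for III, and the middle share turned to 36.4%. By covered bases, ratios were 1.08 for I, 1.002 for III, 1.09 for IV, 0.887 for V and 0.958 for X, and the middle share turned to 34.1%. III was at 0.986 in 10 kb windows. The X share was 56%, 40% and 24% of the strongest 25, 50 and 100, each with an unadjusted permutation p now past the threshold (adjusted p = 0.0615, 0.0491 and 0.0491). The floor under that p changes with the number taken, so these calls do not measure the X share.

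No paired analysis was possible because no values of the input libraries were used here and all results come from interval lists. The alternatives fixed before the data were examined for genomic features, gene assignment, gene lists and the Hox motif were not run, since no annotation of WS220 was used here. Depth is unknown, so weak intervals found in 1 list alone cannot be called absent from the other.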

Other observations

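All tests of this part were chosen only after the result was seen. Gaps between neighbours in each list were compared with those of uniform placements. Placed intervals that overlapped, or lay nearer than any neighbours in the lists, were left out of the uniform counts. Within the range counted, short gaps were more frequent in each list than in the placements. In the combined list, 1206 of 8000 gaps between neighbours (15.1%) were under 1 kb, against a mean of 483 and a highest value of 548 in 1000 uniform placements. The corresponding numbers were 287 gaps against a mean of 98.8 in replicate 1 and 110 against 24.5 in replicate 2. With the pairs left out counted as well, the uniform numbers would be higher. That comparison was not made, so the size of the excess depends on this rule. On chromosome V, 13080960 to 13090870 held 6 intervals of each replicate list, and on chromosome II, 10541850 to 10559744 held 8 of replicate 1 and 7 of replicate 2. Some runs of 1 list had few or no intervals in another. On chromosome V, 15653528 to 15661839 held 6 intervals of replicate 1 and 0 of replicate 2, and on chromosome IV, 16482898 to 16492010 held 11 combined intervals, 2 of replicate 1 and 1 of replicate 2. The strongest interval of replicate 2, on chromosome I at 15063993 to 15067641 (3649 bp, value 0), overlapped no interval of replicate 1 or of the combined list. Its end was the largest on chromosome I in any list, so this interval itself set the extent used for that chromosome.

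The widest interval, 28411 bp on chromosome III at 7521404 to 7549814, was 5.43 times as wide as the next. A signal of 1 library is argued against, since the widest interval of each replicate list lay here and the narrower was 16242 bp. A candidate explanation is extra copies of transgene sequence. Its only grounds are the large width and the shared chromosome with lin-39. A shared chromosome does not place the interval at that gene. Extra copies cannot be told apart from binding, since values of the input libraries were not used here and no lin-39 position on WS220 was used. No biological explanation was tested.

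X held 9 of the 15 strongest combined intervals, but the rotation test, which keeps neighbours together, did not pass (permutation p = 0.0506). Chance is not excluded for these 15, but the test could not decide, since this p sits at the floor set by the outermost X intervals. In this family, 8 of the 18 comparisons passed after adjustment (the 25, 50 and 100 strongest of each replicate and the 50 and 100 strongest of the combined list, permutation test, adjusted p = 0.0491 each). The floor falls as strong intervals near the ends of X are included, so these passes do not measure the X share. A single narrow region of X is argued against, as the X intervals fell in 9 windows of 500 kb. Adjacent windows counted as separate, and the intervals starting at 11093557, 11605262 and 12362713 lay in consecutive windows. A few broader neighbourhoods are therefore not excluded. A signal of 1 library is argued against, as the lower share of the replicates was 53.3%. Wider intervals on X (median 347.5 bp, against 277 bp elsewhere) stay open, because the test with width deciles held (3.18 predicted, one-sided exact p = 0.00110) takes intervals as independent and was run on the intervals in which the X share was noticed. No biological explanation was tested.

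On chromosome IV, 3846848 to 3878099 held a run of 29 combined intervals that covered 56.5% of the span. A signal of 1 library is argued against, since the span held 14 intervals of replicate 1 and 20 of replicate 2. Among 10000 random spans of this length, the mean was 1.11 in replicate 1 and 0.541 in replicate 2, and the highest were 12 and 18. The random spans could overlap this run, so the highest values may come from the run itself and do not show other places as dense. Extra copies of the region in the strain are a candidate explanation. The prediction, written after the data were seen, was coverage as full as that of the chromosome III interval, with raised input. The coverage part was not met, at 56.5%. A single interval fills its own span by definition, so coverage could not decide. Extra copies cannot be told apart from dense binding, since values of the input libraries were not used here. No biological explanation was tested.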
